A study of Drosophila melanogaster with 8 samples.

How the data were processed

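The series measured poly(A) RNA of fly midguts by sequencing on an Illumina HiSeq instrument, with 1 library for each of 8 combinations of genotype, infection and time. Per the submitters' processing notes, adapters were trimmed with cutadapt 1.0, reads were aligned to the dm3 genome with TopHat2 2.0.5 and Bowtie, and expression was estimated with Cufflinks 2.0.2. The annotation, the library strand, the read layout and any pooling of samples are not stated. The values deposited by the authors were taken as FPKM, judged from the values themselves: they are not whole numbers, and the header gives no unit, while the title of the table speaks of normalized counts. Any scaling between libraries beyond FPKM is not stated. No read counts or depths are given, so the depth per library is unknown and no counting interval can be computed. Strand is not stated either, so reads of overlapping genes cannot be told apart.

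The table has 14240 entries. Gene names were taken from the reference by FlyBase identifier: 13487 matched directly, 4 by an older identifier, and 731 kept the identifier as name. A further 18 had no identifier. Entries whose identifier lies on another chromosome in the reference (2) and those whose name occurs more than once (132, under 64 names) were left out, and 14088 genes remained, 12757 of them protein-coding. The reference annotation is of a newer build (dm6), so it served for names, gene types and transcript lengths only, and coordinates are those of the deposited table (dm3, counted from 1). Among genes with a median of at least 20 FPKM, 19 are listed at 0 in some library, 1 of them protein-coding.

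The values were transformed as log2(FPKM + 1), with the scaling as deposited. A pseudocount of 1 shrinks the fold changes of genes near 0, and the fitted change of a gene listed at 0 depends on it. A gene was tested if at least 2 of the 8 libraries reached 1 FPKM, which 8882 genes did. Tests used limma 3.58.1 in R 4.3.3 with a trended prior, and p-values were adjusted by the Benjamini-Hochberg method. A gene is said to rise, fall or differ where its adjusted p was under 0.05. Additive models gave the effects of infection, genotype and time with 4 residual degrees of freedom. Models with 1 interaction term gave genotype by infection, infection by time and genotype by time, and the effects within each level, with 3 residual degrees of freedom. With 1 library per combination, the spread is that between matched pairs; it holds real differences between genotypes and times and is not a replicate spread. For single pairs of libraries only log2 ratios are given, with no test. The models, the filter, the lists and the rule for naming genes were set before the data were examined.

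The lists number 30 and hold 663 genes, of which 624 are in the table. Each list was tested with limma's camera at a preset correlation of 0.01 and again with a correlation estimated per list, and p-values were adjusted over the 30 lists. With the estimated correlation 0 lists passed in any comparison. That version is limited to the residual degrees of freedom of each fit (3 or 4), so it had little power. The lysozyme genes between genotypes had an estimated correlation of 0.015, near the preset value. Their camera adjusted p still went from 9.6e-06 to 0.24. Failing that version therefore says little about any single list. Members were counted over all genes and adjusted over the list alone. For single pairs, the median of a list is given as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins. Genes were named by a fixed rule: JHDM2 in every library, up to 10 genes with the highest and 10 with the lowest log2 change among those that passed and moved the same way in all matched pairs, and up to 4 members with the smallest p of each list described. CG8176, ninaE, Burs, edin and the remaining photoreceptor and secretion genes were chosen after their values were seen.

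Before use, the tests were run on simulated data with 100 genes changed by a log2 of 1 and 100 by 2. The infection test recovered 69% and 89%, with 9 of 167 calls false (5.39%). The genotype by infection test recovered 4% and 41%, with 1 of 46 calls false (2.17%). Alternatives covered median-ratio size factors, quantile normalization, pseudocounts of 0.1 and 5, no filter on low values, a filter 5 times higher, a robust prior, a model with all pairwise interactions, lists without near-identical copies, and leaving out each library in turn. Protein-coding genes alone, the matched pairs as blocks, the lists without each library, and the alternatives for effects within each level were added after seeing the data. Random draws and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.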

Results

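Poly(A) RNA from Drosophila melanogaster midguts was sequenced in 8 libraries. Flies of a control genotype and flies labelled JHDM2 knockdown were either left uninfected or given Ecc15 (Erwinia carotovora 15, a bacterium that infects the fly gut when eaten), and were sampled at 4 h or 16 h. Each of the 8 combinations has 1 library, so no value has a replicate. The 8 FPKM columns sum to between 837161 and 1253062, and the read depth behind them is unknown. The highest sum belongs to the control Ecc15 4 h library, where the microRNA gene mir-2a-1 has the highest value of all and is at 0 in the other libraries. The 10 genes with the highest FPKM, mir-2a-1 among them, take 40.4% of that library's sum. The number of reads behind the mir-2a-1 value is unknown. Among protein-coding genes the share is 14.2%. Between 8340 and 8725 genes reach 1 FPKM per library.

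JHDM2, named Kdm3 in the current annotation (FBgn0037703, dm3 chromosome arm 3R, 5341731 to 5346660), encodes a histone demethylase of the JmjC family. Its level runs against the label. It stood at 5.70, 5.06, 4.11 and 6.69 FPKM in the control libraries (uninfected 4 h and 16 h, then Ecc15 4 h and 16 h). In the libraries labelled JHDM2 knockdown it stood at 205.5, 325.5, 269 and 259 FPKM in the same order. The means were 5.39 ± 1.08 and 265 ± 49.2 FPKM (SD, n = 4 each), a ratio of 49.1, and the log2 difference was 5.38 ± 0.16 (SE, adjusted p = 0.000146). The gene's span overlaps that of CG8176, which differed by -0.02 (adjusted p = 0.963). Ecc15 left Kdm3 at a log2 change of 0.00 (adjusted p = 0.991). The series asks what JHDM2 knockdown changes in the infected midgut. Because Kdm3 RNA is higher where the label says knockdown, every direction between genotypes is given here as libraries labelled JHDM2 knockdown over control libraries.

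After Ecc15 the antimicrobial peptide genes, effectors of the humoral immune response, rose. DptA, a diptericin gene, went from 9.09 to 496 FPKM at 4 h and from 3.05 to 436 FPKM at 16 h in control flies. In the libraries labelled JHDM2 knockdown it went from 10.7 to 129 FPKM at 4 h and from 0.814 to 654 FPKM at 16 h. Its log2 change over the 4 matched pairs was 6.09 ± 0.73 (SE, adjusted p = 0.0039). CecA1 rose by 3.45 ± 0.19 and CecA2 by 2.70 ± 0.16 (adjusted p = 0.00132 for both). AttD rose by 5.63 ± 0.92 (adjusted p = 0.00801), from 10.4 to 272 FPKM in the control pair at 4 h. Of the 13 antimicrobial peptide genes tested, 11 rose and 0 fell, also 11 and 0 adjusted over the list alone. Their median log2 change was 2.70 (camera adjusted p = 3.9e-06, and adjusted p = 0.61 with an estimated correlation). In the single pairs the list's median was 1.57 and 2.24 in control flies at 4 h and 16 h, and 2.60 and 3.76 in the libraries labelled JHDM2 knockdown. Each of these medians lies at percentile 100 of matched random lists. Attacin and cecropin copies can share reads, so the split between copies is uncertain.

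**Figure D1:**
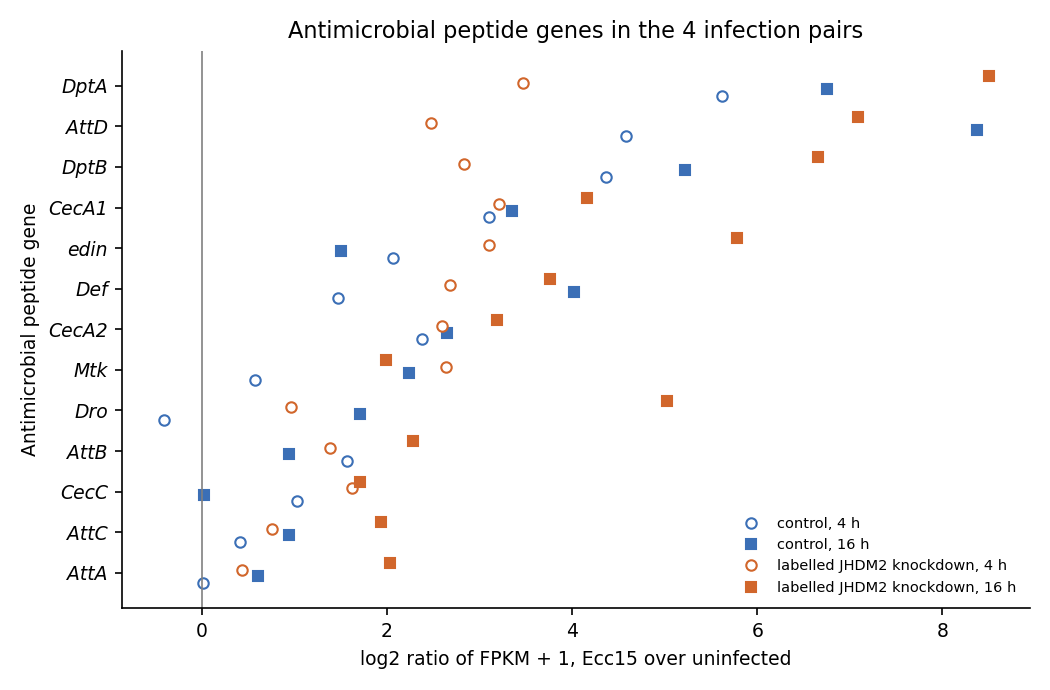
Log2 ratio of FPKM + 1 (Ecc15 over uninfected, horizontal axis) of the 13 tested antimicrobial peptide genes (vertical axis), with 1 point for each of the 4 pairs of libraries. DptA has the highest log2 change over the 4 pairs (6.09), and the list's medians run from 1.57 to 3.76.

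Single genes of peptidoglycan sensing and of cytokine and JNK signalling rose, while the lists for JAK-STAT and JNK did not pass. PGRP-SD, a peptidoglycan recognition gene, rose by 4.45 ± 0.37 (adjusted p = 0.00195), from 6.32 to 119 FPKM in the control pair at 4 h. PGRP-LB, PGRP-LF and the IMD inhibitor gene pirk rose by 1.79, 1.84 and 2.97. Of 21 genes of the IMD pathway and peptidoglycan recognition, 9 rose and 2 fell (11 and 2 adjusted over the list alone), with a camera adjusted p of 0.017 and an adjusted p = 0.61 with an estimated correlation. The cytokine gene upd3 rose by 2.97 ± 0.25 (adjusted p = 0.00203), from 1.99 to 33.7 FPKM in the control pair at 4 h, and the JAK-STAT target Socs36E rose by 2.20. In the JAK-STAT list 7 of 19 genes rose and 2 fell (7 and 3 adjusted over the list alone, camera adjusted p = 0.13). In the JNK and wound list 7 of 17 rose and 3 fell (8 and 3 adjusted over the list alone, camera adjusted p = 0.15), with Ets21C at 2.24 and Gadd45 at 2.10, while egr fell by 0.75 and wgn fell by 1.31. The Toll list held 1 gene that rose and 4 that fell among 14 (1 and 5 adjusted over the list alone, camera adjusted p = 0.15).

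Some stress and detoxification genes rose and others fell. GstD8, a glutathione S-transferase gene, rose by 4.91 ± 0.52 (adjusted p = 0.00286), from 73.2 to 1384 FPKM in the control pair at 4 h. GstD1, GstD9, GstD10 and GstD4 rose by 1.60, 2.17, 2.29 and 2.64; reads can be shared within this cluster. Of 37 oxidative stress and detoxification genes, 15 rose and 5 fell (17 and 6 adjusted over the list alone), with a camera adjusted p of 0.022 and an adjusted p = 0.61 with an estimated correlation. Among 16 heat shock genes 5 rose and 0 fell, also adjusted over the list alone (median 0.90, camera adjusted p = 0.0021, adjusted p = 0.61 with an estimated correlation), with Hsc70-3 at 1.51 and stv at 0.92. In the single pairs the heat shock median was 1.23 and 1.04 in control flies at 4 h and 16 h. In the libraries labelled JHDM2 knockdown it was 0.53 and 0.27, the latter at percentile 88.5 of matched random lists. Cyp6a2, a cytochrome P450 gene, fell by 3.09 ± 0.35 (adjusted p = 0.00337).

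Genes of the list for the acid-secreting copper cell region fell, as did some genes of muscle. Most of that list encodes subunits of the vacuolar proton pump, so its fall is not that of copper cell markers alone. All 9 tested genes of the list fell, also adjusted over the list alone, with a median of -0.78 (camera adjusted p = 3.2e-06, adjusted p = 0.38 with an estimated correlation). CAH1, a carbonic anhydrase gene, fell by 1.33, the homeobox gene lab fell by 1.48, and Ptx1 fell by 0.98. Of 16 visceral muscle genes 9 fell and 1 rose, also adjusted over the list alone (median -0.57, camera adjusted p = 0.0014, adjusted p = 0.61 with an estimated correlation), with Tm2 at -0.83 and up at -0.87. The lipid synthesis gene ACC fell by 1.10, the carnitine palmitoyltransferase gene whd fell by 1.26, and mira, of the stem cell and enteroblast list, fell by 1.92. The largest decrease among the named genes was that of CG8745 (FBgn0036381), which fell by 5.05 ± 0.16 (adjusted p = 0.00021), from between 261 and 492 FPKM in the uninfected libraries to between 7.16 and 14.1 FPKM after Ecc15.

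The genes of the cytoplasmic and mitochondrial ribosome moved apart. Of 80 cytoplasmic ribosomal protein genes 55 fell and 0 rose (70 and 0 adjusted over the list alone), with a median of -0.36 (camera adjusted p = 3.1e-15, adjusted p = 0.61 with an estimated correlation). After quantile normalization 12 of them fell, and with median-ratio size factors 45. RpL22 fell by 0.74 and RpL10Ab fell by 0.54. Of 69 mitochondrial ribosomal protein genes 40 rose and 0 fell (52 and 0 adjusted over the list alone), with a median of 0.46 (camera adjusted p = 5.3e-11, adjusted p = 0.61 with an estimated correlation). After quantile normalization 35 of them rose. mRpL30 rose by 0.75 and mRpL18 by 0.71.

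Other lists had few changed members or members that went both ways. Among digestive genes, 6 of 18 for carbohydrates and lipids fell and 0 rose, and of 31 protease genes 2 rose and 2 fell. In the lists for lipid storage, for insulin and fasting, and for stem cells and enteroblasts, 1 gene rose in each, and 6 of 17, 5 of 10 and 5 of 12 fell. Of the EGFR list 3 of 15 rose and 1 fell, of the clock list 1 of 9 rose and 3 fell, and of the peritrophic matrix list 1 of 10 rose and 2 fell. Over both times 3 of 37 cell cycle genes rose and 0 fell. Among the 11 JmjC and LSD1 demethylase genes 1 rose and 3 fell, with Kdm4B at -0.78 and Utx at -0.66, and of 7 H3K9 methyltransferase and HP1 genes 1 fell. The Duox list had 1 gene of 8 that rose, the enteroendocrine list 1 of 17 that fell, and the lysozyme list 0 of 7 that changed. Markers of tissues next to the midgut gave 0 changed genes of 7 for fat body and 0 of 10 for the reproductive tract. Among the haemocyte, Malpighian tubule and tracheal markers 1 of 10, 2 of 10 and 1 of 3 fell. Adjusted over the list alone, 6 genes fell in each of the insulin and stem cell lists, 1 cell cycle gene rose, and 0 enteroendocrine, 0 haemocyte and 1 Malpighian tubule gene fell. Camera gave these lists adjusted p values between 0.0613 and 0.999.

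Over all 8882 genes tested, 2899 changed after Ecc15 with limma at an adjusted p under 0.05, 1605 up and 1294 down. Of these, 324 rose and 280 fell at least 2-fold. The excess of rising genes depended on the scaling: 1503 rose and 1503 fell with median-ratio size factors, and 1396 rose and 1469 fell with quantile normalization. The spread behind this test is what the additive model leaves over. It holds the differences between the 4 matched pairs and the genotype by time interaction, so real effects of genotype and time are part of it. The count was 1605 without the labelled JHDM2 knockdown Ecc15 16 h library, 1672 without the control Ecc15 16 h library and 1771 without the control Ecc15 4 h library. It was 1797 without the labelled uninfected 16 h library, 1818 without the control uninfected 16 h library and 1845 without the control uninfected 4 h library. The genes named above for Ecc15 kept an adjusted p under 0.05 in every fit without 1 library.

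The response at 4 h differed from that at 16 h in digestive and cell cycle genes, among others. Mal-A6, a maltase gene, went from 1604 to 440 FPKM at 4 h and from 1815 to 1353 FPKM at 16 h in control flies, and the fall was deeper at 4 h by 1.49 ± 0.12 (adjusted p = 0.0228). Of 18 carbohydrate and lipid digestion genes 7 fell and 0 rose at 4 h (0 and 9 up and down adjusted over the list alone, median -1.36, camera adjusted p = 9.1e-05, adjusted p = 0.67 with an estimated correlation). At 16 h 2 rose and 2 fell (median -0.13, camera adjusted p = 0.56). Without 1 library the list's median at 4 h ran from -1.52 (control Ecc15 4 h left out) to -0.74 (labelled Ecc15 4 h left out). The difference itself passed for 4 genes over all genes and for 8 adjusted over the list alone (median 1.27, camera adjusted p = 2.4e-05, adjusted p = 0.96 with an estimated correlation). Lip4, Mal-A1 and Mal-A2 were the others, at 1.67, 1.20 and 1.21. The near-identical trypsin genes gammaTry and deltaTry gave 2.57 and 2.54. The Mal-A6 difference passed again without the control Ecc15 4 h library (adjusted p = 0.0427) or the labelled Ecc15 4 h library (adjusted p = 0.0406). Without any 1 of the other 6 libraries it did not (adjusted p between 0.105 and 0.143), and those of Lip4, Mal-A1 and Mal-A2 passed in no fit without 1 library.

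Of 37 cell cycle genes 20 rose at 16 h. PCNA, the replication clamp gene, went from 7.47 to 78.5 FPKM at 16 h in control flies and from 7.99 to 53.2 FPKM in the libraries labelled JHDM2 knockdown, against 21.1 to 19.8 and 11.5 to 16.2 FPKM at 4 h. Its response was larger at 16 h by 2.72 ± 0.32 (adjusted p = 0.0371), and those of RnrS and Mcm6 by 2.16 ± 0.17 and 1.59 ± 0.20. At 16 h 0 members fell (22 rose and 0 fell adjusted over the list alone, median 1.24, camera adjusted p = 7.5e-06, adjusted p = 0.65 with an estimated correlation). At 4 h 1 rose and 3 fell, also adjusted over the list alone (median -0.27, camera adjusted p = 0.20). The difference passed for 3 genes over all genes and for 22 adjusted over the list alone (median 1.35, camera adjusted p = 5.0e-10, adjusted p = 0.96 with an estimated correlation). The list's single-pair median at 4 h was -0.80 in control flies and 0.29 in the libraries labelled JHDM2 knockdown. In the same control pair the medians of the reproductive tract, Malpighian tubule and fat body markers were -1.30, -1.27 and -1.01, and in the labelled pair 0.49, 0.53 and 0.57. With quantile normalization the adjusted p of the PCNA difference was 0.0504. That difference passed in no fit without 1 library (adjusted p between 0.071 and 0.186), nor did that of Mcm6, and that of RnrS passed without the control or the labelled Ecc15 4 h library (adjusted p = 0.0427 and 0.0406). The rise of PCNA at 16 h itself passed in all 8.

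The cell cycle list was fitted again without each library, a check chosen after seeing the data. Without the control uninfected 4 h library its median at 4 h was 0.19, and the difference between times was 0.87 (0 of 37 passing, camera adjusted p = 1.5e-08, adjusted p = 0.81 with an estimated correlation). Camera called the list at 4 h without the labelled Ecc15 4 h library (median -0.57, camera adjusted p = 0.031) and without the labelled uninfected 4 h library (-0.71, 9.4e-06), but not with an estimated correlation (adjusted p = 0.71 and 0.65). At 16 h 3 members rose without the control Ecc15 16 h library, 4 without the control uninfected, 1 without the labelled Ecc15 and 10 without the labelled uninfected 16 h library, with medians between 1.05 and 1.33. For the carbohydrate and lipid digestion genes, 4 fell at 4 h without the control or without the labelled uninfected 4 h library.

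**Figure D2:**
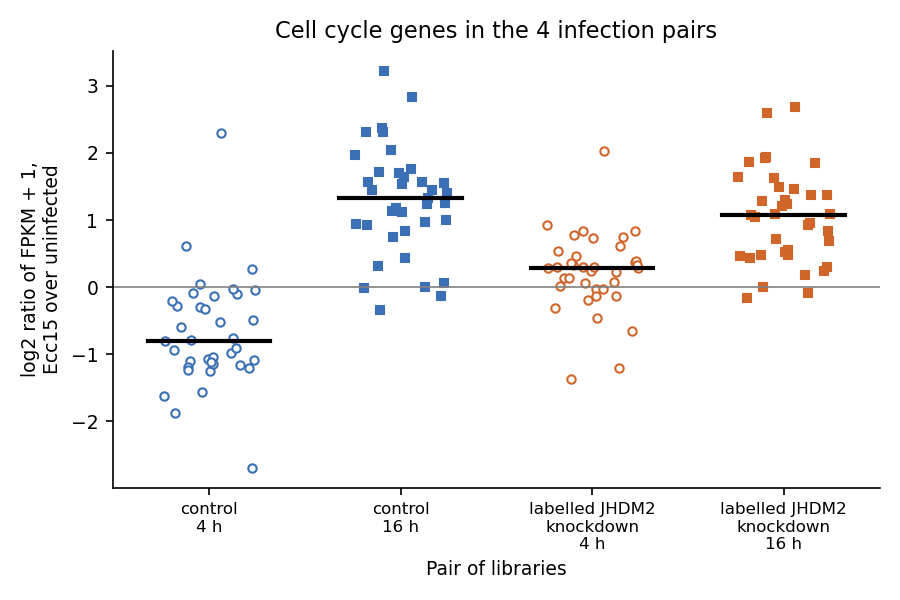
Log2 ratio of FPKM + 1 (Ecc15 over uninfected, vertical axis) of the 37 tested cell cycle genes in the 4 pairs of libraries (horizontal axis), with 1 point for each gene and a bar at the median. The medians are -0.80 and 1.34 in control flies at 4 h and 16 h, and 0.29 and 1.07 in the libraries labelled JHDM2 knockdown.

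Hsc70-3, the chaperone of the endoplasmic reticulum, rose by 2.23 ± 0.09 at 4 h and by 0.78 at 16 h, and the difference was -1.46 ± 0.13 (adjusted p = 0.0292). Among heat shock genes 6 of 16 rose at 4 h and 4 at 16 h (camera adjusted p for the difference = 0.21). The Hsc70-3 difference passed again without the control Ecc15 4 h library (adjusted p = 0.0446) but not without any 1 of the other 7, where its adjusted p lay between 0.0556 and 0.163. The Hsc70-3 rise at 16 h ended without the control Ecc15, the control uninfected or the labelled Ecc15 16 h library (adjusted p = 0.0555, 0.0511 and 0.068). Vha100-4, a subunit gene of the vacuolar proton pump, fell by 1.24 at 4 h and fell by 3.76 at 16 h, a difference of -2.52 ± 0.26. Its fall at 4 h ended without the control or the labelled uninfected 4 h library (adjusted p = 0.0736 and 0.077). All 9 tested genes of the copper cell list fell at both times. MtnC, a metallothionein gene, gave a difference of -1.90 (adjusted p = 0.0421). It was the 1 of 37 oxidative stress genes that passed for the difference, also adjusted over the list alone (median -0.31, camera adjusted p = 0.00043, adjusted p = 0.96 with an estimated correlation). Of the antimicrobial peptide genes 7 rose at 4 h and 11 at 16 h, with medians of 2.08 and 3.36, but for the difference 0 of 13 passed (median 1.06, camera adjusted p = 0.058). Cytoplasmic ribosomal protein genes fell in 8 of 80 at 4 h and in 72 at 16 h (1 and 74 adjusted over the list alone). For the difference 0 passed (median -0.30, camera adjusted p = 8e-21, adjusted p = 0.96 with an estimated correlation). These counts are for the scaling as deposited. Over both times fewer genes of this list fell after quantile normalization, as given above.

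**Figure D3:**
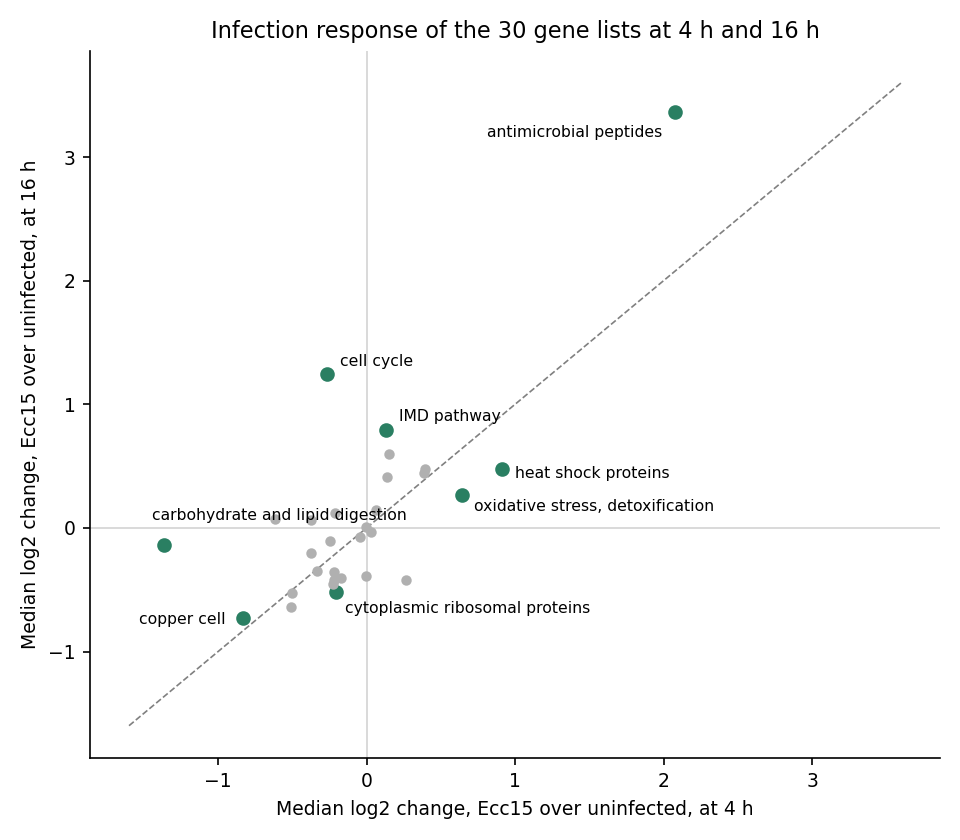
Median log2 change after Ecc15 of the 30 gene lists at 4 h (horizontal axis) and at 16 h (vertical axis), with 1 point for each list and a dashed line where both are equal. Cell cycle genes lie at -0.27 and 1.24, carbohydrate and lipid digestion genes at -1.36 and -0.13, and antimicrobial peptide genes at 2.08 and 3.36.

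In all, 1911 genes changed at 4 h (1013 up, 898 down) and 2790 at 16 h (1749 up, 1041 down). Of these, 1134 changed at both times, 615 up at both and 491 down at both. The difference between times passed for 111 genes, 66 higher and 45 lower at 16 h relative to 4 h, and 1997 had an unadjusted p under 0.05. With median-ratio size factors these became 65 and 83, with quantile normalization 56 and 65, and at 16 h the split became 1405 up and 1439 down, and 1292 up and 1384 down. The median of all genes in the difference was 0.09 as deposited, -0.02 with median-ratio size factors and -0.03 with quantile normalization. Of the 111 genes, 41 passed again without the control Ecc15 4 h library and 31 without the labelled JHDM2 knockdown Ecc15 4 h library. Without any 1 of the other 6 libraries 1 or 2 did. The count at 4 h was 419 without the labelled uninfected 4 h library and 565 without the control uninfected 4 h library. It was 707 and 1180 without the control and labelled Ecc15 4 h libraries, and 1115 and 1110 without those at 16 h. The count at 16 h was 174 and 402 without the labelled and control Ecc15 16 h libraries, and 1015 and 460 without the labelled and control uninfected 16 h libraries.

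Between the genotypes, some genes were nearly absent in 1 genotype and present in the other. CG7900 (3R, 3919846 to 3930805) was at 0.0374 to 0.341 FPKM in control libraries and at 13.7 to 16.3 FPKM in the libraries labelled JHDM2 knockdown (log2 difference 3.76 ± 0.13, adjusted p = 0.000146). The potassium channel gene sand (2R, 3979203 to 3984450) was at 0.451 to 0.977 FPKM and at 13.2 to 16.1 FPKM (3.30 ± 0.15, adjusted p = 0.000542). The eye pigment transporter gene w (X, 2684632 to 2690499) was at 1.10 to 5.49 FPKM and at 29.8 to 48.9 FPKM (3.26 ± 0.24, adjusted p = 0.00475). CG4650 differed by 4.49 ± 0.30 (adjusted p = 0.00346). CG30289 (2R, 17407960 to 17409338) went the other way, at 18.3 to 31.1 FPKM in control libraries and at most 0.226 FPKM in the libraries labelled JHDM2 knockdown (-4.56 ± 0.15, adjusted p = 0.000146). CkIIalpha-i3 and CG32437 differed by -1.70 and -1.69. These genes kept an adjusted p under 0.05 without any 1 of the 8 libraries.

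**Figure D4:**
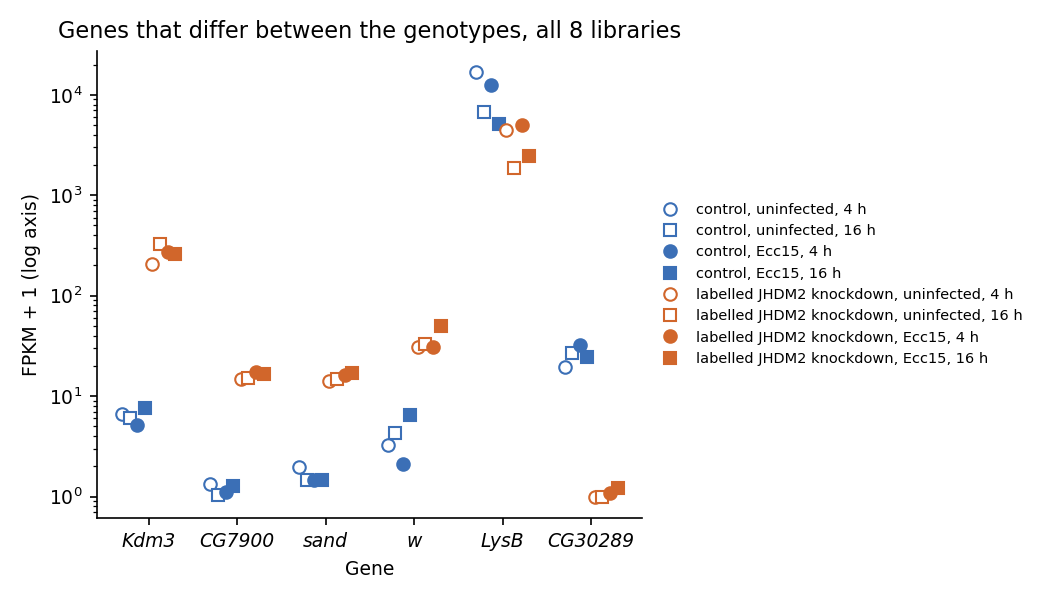
FPKM + 1 on a log axis (vertical) of 6 genes (horizontal) in all 8 libraries, with 1 point for each library, coloured by genotype and filled for Ecc15. Kdm3 lies at 4.11 to 6.69 FPKM in control libraries and at 205.5 to 325.5 FPKM in the libraries labelled JHDM2 knockdown.

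Neighbouring lysozyme genes were lower in the libraries labelled JHDM2 knockdown. LysB was at 5118 to 16870 FPKM in control libraries and at 1852 to 5055 FPKM in the labelled ones (-1.54 ± 0.17, adjusted p = 0.02), and LysC, LysD and LysE gave -1.40, -1.13 and -1.10. Of the 7 lysozyme genes 4 were lower and 0 higher over all genes (5 and 0 adjusted over the list alone), with a median of -1.13 (camera adjusted p = 9.6e-06, adjusted p = 0.24 with an estimated correlation). The single-pair medians were -1.41 and -1.24 in uninfected flies and -0.96 and -1.06 after Ecc15. These genes are near-identical neighbours on 3L, so they count as fewer than 4 independent results. The LysB call held without the control Ecc15 4 h library (adjusted p = 0.0382) and without the labelled Ecc15 16 h library (adjusted p = 0.0324). It ended without any 1 of the other 6 (adjusted p between 0.0702 and 0.104), and with quantile normalization (adjusted p = 0.0693). LysC and LysD held without the control or the labelled Ecc15 4 h library and ended without any 1 of the other 6, and LysE held without the labelled Ecc15 4 h library alone.

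Hsp70Ba, a heat shock gene, was higher by 2.87 ± 0.32 (adjusted p = 0.0219), and phu, which lies near Kdm3, by 2.76 ± 0.30 (adjusted p = 0.02). Both calls held without the control Ecc15 4 h library or the labelled uninfected 16 h library and ended without any 1 of the other 6 libraries, where the adjusted p lay between 0.0714 and 0.109 for phu and between 0.0532 and 0.119 for Hsp70Ba. The medians of marker lists for other tissues went both ways. Camera called the haemocyte markers (median -0.50, 0 of 10 passing, camera adjusted p = 0.0073) and visceral muscle (-0.21, 0 of 16, 0.026). It did not call the Malpighian tubule (-1.02, 1 of 10 lower), reproductive tract (-0.25), fat body (0.11) and tracheal markers (0.39), and the Malpighian tubule median was 0.91 in the Ecc15 4 h pair. Of the other lists that camera called, 1 of 16 heat shock genes passed (2 adjusted over the list alone, median 0.14, camera adjusted p = 0.0021), and 0 of 31 protease genes (0.11, 0.0016) and 0 of 80 cytoplasmic ribosomal protein genes (0.07, 5.5e-06). With an estimated correlation these adjusted p values were between 0.863 and 0.903. The single-pair medians of the heat shock genes were 0.73 and 0.72 in uninfected flies at 4 h and 16 h. After Ecc15 they were -0.15 and -0.002. No antimicrobial peptide gene passed. AttC, the member with the smallest p, gave 1.01 (adjusted p = 0.283). In all, 46 genes differed between the genotypes, 25 higher and 21 lower in the libraries labelled JHDM2 knockdown, while 1040 had an unadjusted p under 0.05 against 444 expected by chance. With the matched pairs as blocks, a model chosen after seeing the data, 81 differed, 43 of the 46 among them. The count was 12 without the control uninfected 4 h library, 78 without the control Ecc15 4 h library and between 15 and 23 without any 1 of the other 6. Within uninfected flies 6 genes passed (4 higher, 2 lower) and after Ecc15 13 passed (6 higher, 7 lower). Without any 1 library these ran from 0 to 15 and from 0 to 7.

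No gene passed for a difference between the genotypes in their response to Ecc15 (0 of 8882 with limma, 238 with an unadjusted p under 0.05 against 444 expected by chance). On simulated data this test recovered 41% of genes with a log2 difference of 2 and 4% of those with 1. In the real data its spread also holds changes of the Ecc15 and genotype effects with time, which can hide such differences. The largest protein-coding differences among the genes with the smallest p were Arr2 at 4.69 (adjusted p = 0.297) and Jon65Aii at -2.91 (adjusted p = 0.158), and neither passed. Within control flies 707 genes changed after Ecc15 (409 up, 298 down) and within the libraries labelled JHDM2 knockdown 286 (137 up, 149 down). Of these, 234 changed in both and 233 the same way. With median-ratio size factors the splits were 359 and 412, and 150 and 241, and with quantile normalization 366 and 460, and 120 and 210. Without any 1 of the 8 libraries the counts were at most 354 and 33. Of the 1306 genes that moved at least 2-fold in the control pair at 4 h, 975 (74.7%) went the same way in the labelled pair, and at 16 h 1110 of 1226 (90.5%) did. Of the genes chosen in the labelled pair instead, 751 of 885 (84.9%) went the same way in control flies at 4 h, and 1025 of 1152 (89.0%) at 16 h.

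In that difference 0 members of any list passed over all genes. Adjusted over the list alone, 1 JAK-STAT gene was higher (camera adjusted p = 0.98, adjusted p = 0.99 with an estimated correlation) and 1 protease gene lower (camera adjusted p = 0.75, adjusted p = 0.94 with an estimated correlation). Camera with its preset correlation gave small p values for 10 of the 30 lists, and 0 passed with an estimated correlation. The antimicrobial peptide genes had a median of 0.58 (camera adjusted p = 0.00023), the heat shock genes -0.83 (0.00019), the Malpighian tubule markers 1.34 (0.00018) and the haemocyte markers 0.63 (0.00018). With an estimated correlation each of these 4 had an adjusted p = 0.65. The immune gene edin, chosen after its values were seen, did not pass for this difference. It went from 0.408 to 76.5 FPKM at 16 h in the libraries labelled JHDM2 knockdown. In control flies at 16 h it was listed at 0 in the uninfected library and at 1.84 FPKM after Ecc15. At 4 h the markers of other tissues moved apart between the genotypes. The Malpighian tubule median after Ecc15 was -1.27 in control flies at 4 h and 0.53 in the labelled pair, the fat body median -1.01 and 0.57, and the reproductive tract median -1.30 and 0.49. Between the genotypes at 16 h, in pairs that share no library, the Malpighian tubule median was -2.03 in uninfected flies and -1.16 after Ecc15. The rhodopsin gene ninaE stood at 104 FPKM in the control uninfected 4 h library and at 46.8 FPKM in the labelled Ecc15 4 h library, against 1.43 to 16.6 FPKM in the other 6 libraries.

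For a genotype difference that changed between 4 h and 16 h, 3 genes passed (261 with an unadjusted p under 0.05). They are the small nucleolar RNA genes snoRNA:Psi28S-2622, snoRNA:Psi18S-841a and snoRNA:Psi18S-525f, each listed at 0 in 6 of the 8 libraries. Without any 1 library 0 genes passed. The visceral muscle list had a median of -0.62 (0 of 16 over all genes, 12 lower adjusted over the list alone, camera adjusted p = 4.4e-15, adjusted p = 0.31 with an estimated correlation). The mitochondrial ribosomal protein list had a median of -0.39 (0 of 69, camera adjusted p = 7.7e-22, adjusted p = 0.53 with an estimated correlation). In all, camera called 11 lists here, and 0 with an estimated correlation. The other 9 medians were -1.65 for Malpighian tubule markers (camera adjusted p = 0.0038), 0.59 for antimicrobial peptides (0.0064), 0.54 for heat shock genes (0.0015), 0.28 for oxidative stress (0.0001), 0.27 for carbohydrate and lipid digestion (0.0058), 0.22 for the cell cycle (0.0075), 0.19 for proteases (0.00019), 0.15 for JAK-STAT (0.00021) and 0.10 for haemocyte markers (0.017). In these 9 lists 0 members passed over all genes or adjusted over the list alone, and with an estimated correlation the adjusted p lay between 0.31 and 0.88.

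Between 4 h and 16 h, over both genotypes and infection states, the clock gene tim rose. It was at 36.3 to 56.7 FPKM at 4 h and at 88.4 to 238 FPKM at 16 h (1.57 ± 0.14, adjusted p = 0.0451). CG3739 rose, from 121 to 735 FPKM in uninfected control flies (adjusted p = 0.0267), and Vha100-2 from 182 to 348 FPKM there (adjusted p = 0.0451), and the stress-induced gene TotA fell by 2.12 ± 0.17 (adjusted p = 0.0445). With median-ratio size factors the adjusted p of tim was 0.0553. With the matched pairs as blocks, a model chosen after seeing the data, all 4 calls of this comparison ended (adjusted p of tim = 0.0933). These 4 were the genes that passed (1815 with an unadjusted p under 0.05). The tim, Vha100-2 and TotA calls ended without any 1 of the 8 libraries (adjusted p of tim between 0.0883 and 0.209), and that of CG3739 held without the labelled Ecc15 4 h library (adjusted p = 0.00768) or the labelled Ecc15 16 h library (adjusted p = 0.0212). Of the 69 mitochondrial ribosomal protein genes 0 passed over all genes and 56 were higher at 16 h adjusted over the list alone (median 0.46, camera adjusted p = 8e-27, adjusted p = 0.37 with an estimated correlation). The haemocyte markers had a median of -0.999 (0 of 10 over all genes, 8 lower adjusted over the list alone, camera adjusted p = 3.3e-07, adjusted p = 0.37 with an estimated correlation). In all, camera called 15 lists between the times, and 0 with an estimated correlation. Other tissue markers among them had medians of -1.37 (reproductive tract, 0 of 10 over all genes), -0.86 (fat body, 0 of 7) and -0.36 (tracheal, 0 of 3). The medians of the rest were -0.82 for lysozymes, 0.67 for carbohydrate and lipid digestion, -0.27 for proteases, -0.24 for the IMD pathway, -0.20 for Toll, -0.28 for insulin and fasting, -0.16 for oxidative stress, -0.12 for EGFR, -0.12 for enteroendocrine markers and 0.07 for cytoplasmic ribosomal proteins, with 0 members of each passing over all genes. Adjusted over the list alone, 3 carbohydrate and lipid digestion genes were higher at 16 h, and lower were 6 protease, 5 oxidative stress, 4 lysozyme, 4 IMD, 4 Toll, 3 EGFR, 2 fat body and 1 tracheal genes. For these 9 lists the camera adjusted p lay between 0.00065 and 0.032, and between 0.37 and 0.56 with an estimated correlation.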

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

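The tests of the raised Kdm3 level and of the chromosome positions of the genes that differ between genotypes, and the scaling value for time, were chosen only after those results were seen, while the splits of the libraries and the tests on transcript length and scaling were written down before their outcomes were computed.

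The response to Ecc15 differed between 4 h and 16 h in 111 genes by the interaction test. Among protein-coding genes the response was higher at 16 h for CG31789 (3.81), CG5883 (3.11), CG10559 (2.93), WRNexo (2.75), Mov10 (2.74), CG10898 (2.74), PCNA (2.72), RnrS (2.16) and Mcm6 (1.59). It was also higher for Mal-A6 (1.49), Lip4 (1.67), Mal-A1 (1.20), Mal-A2 (1.21), gammaTry (2.57) and deltaTry (2.54). It was lower at 16 h for CG9498 (-3.18), CG31259 (-2.86), Vha100-4 (-2.52), Mdr50 (-2.47), CG15096 (-2.24), CG9416 (-2.22), CG4991 (-2.21), MtnC (-1.90), CG31288 (-1.89) and Hsc70-3 (-1.46). Small nucleolar RNA genes gave the most extreme values, snoRNA:Me28S-G2703a at 12.77, snoRNA:Me28S-G3255b at 12.38, snoRNA:229 at 5.63 and snoRNA:Psi28S-1837b at -5.475, and each of these is listed at 0 in at least 5 of the 8 libraries, so its fitted value depends on the pseudocount. Of the 32 splits of the libraries for this term, 1, the real one, gave as many genes, and the highest other gave 4. Any real effect adds to the leftover spread of the other splits and lowers their counts, so this test cannot exclude a random arrangement. Genotype by time passed for 3 genes, snoRNA:Psi28S-2622 (5.53), snoRNA:Psi18S-841a (5.53) and snoRNA:Psi18S-525f (5.43). Of 32 splits, 4 gave as many, so chance is not excluded for these 3. The highest other, with 111, is the infection by time arrangement and not a random one.

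For the Ecc15 effect 1 of 33 splits gave as many genes as the real 2899, the real one itself, and the highest other gave 4. For the genotype effect this was 1 of 33, with 46 genes against 28 in the highest other split, which parts the libraries by infection and time together. For time it was 1 of 33, with 4 genes against 3. In these splits too, any real effect adds to the leftover spread of the others and lowers their counts. For genotype by infection the real count is 0, so 32 of 32 splits must give at least as many and this test says nothing about that result.

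Kdm3 stood higher in the libraries labelled JHDM2 knockdown, where a lower level would be looked for. The tables argue against a single wrong label, since the lowest labelled value is 30.71 times the highest control value, and against a gain of the whole region, since the 11 tested genes within 30 kb of Kdm3 have a median log2 difference of -0.032. The exception is phu, at 2.76 (adjusted p = 0.02), so a change in part of the region is not excluded. A candidate explanation is Kdm3 sequence transcribed from a transgene, such as a hairpin or an expression construct, because w, the usual marker gene of fly transgenes, is higher in the same libraries by 3.258. A w difference between the stocks without such a transgene, an exchange of the genotype names of whole groups, and a true rise of JHDM2 all stay open, since FPKM per gene cannot tell hairpin RNA from messenger RNA.

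The 46 genes that differ between the genotypes lie closer together than random sets do. Of them, 17 lie within 100 kb of another, against a median of 4 and a 95th percentile of 10 in 10000 random sets (permutation p = 0.0002, one-sided). After the lysozyme genes and the Hsp70 locus are left out, 10 of 40 do so against a 95th percentile of 8 (permutation p = 0.0156, one-sided), and with Kdm3 and its neighbour phu also left out 8 of 38 do so, against a 95th percentile of 8 (permutation p = 0.0511, one-sided). Gene family clusters and the Kdm3 locus are therefore not excluded as the source of the closeness, and other families were not tested. Stocks that differ in particular chromosome regions may account for part of the list, and an effect of JHDM2 on neighbouring genes stays open, because genotype and stock are the same 4 against 4 libraries.

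Mitochondrial ribosomal protein genes were higher after Ecc15 (40 of 69 passing), and their median was higher at 16 h (0 of 69 passing over all genes). Their transcripts are short (median 774 bases), and lists matched on length and expression had a median of 0.27 for Ecc15 and 0.20 for time, so part of the shift is shared with other short transcripts. The list's 0.46 lies at percentile 99.96 of the matched lists for Ecc15 and at 100 for time, so its shift is larger than theirs. Its members vary together (estimated correlation 0.72), which random lists do not reproduce, so the percentile cannot settle whether length is the whole cause. After quantile normalization the median is 0.369 for Ecc15 and 0.39 for time, which argues against scaling between libraries as the whole cause, although 0 of the 69 genes passed for time under any scaling. A coordinated rise of mitochondrial translation genes may remain as a biological reading. The camera call does not hold with an estimated correlation (adjusted p = 0.61 for Ecc15 and 0.37 for time). No list passed that version in any comparison, the antimicrobial peptides after Ecc15 included, so it cannot decide for or against this reading.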

How the results depend on the processing

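The alternatives for protein-coding genes alone, for effects within each level, for matched pairs as blocks and for the lists without each library were chosen after seeing the data. The others were set earlier. The labels give no replicate numbers, but each library has partners that differ in 1 factor. With these 4 matched pairs as blocks (3 residual degrees of freedom), 2279 genes passed for Ecc15, 81 for genotype (43 of the 46 among them) and 1 for time (0 of the 4), and 8, 5 and 16 lists passed. Count-based tests were not run because the table holds no counts, and TMM was replaced by median-ratio size factors for the same reason. No named gene that passed had the opposite sign under any alternative. The balance of rising and falling genes did turn with scaling, as given in the results for Ecc15 over all libraries, at 16 h and in control flies, and for infection by time. Among the named genes, 465 of the results kept their direction and their side of the threshold with median-ratio size factors, 449 with quantile normalization, 460 and 448 with pseudocounts of 0.1 and 5, and 272 with no filter on low values. Without 1 library, between 241 and 354 did. With median-ratio size factors 17 named results no longer passed and 4 that had not passed changed sign, and with no filter 214 no longer passed. Most results not kept without 1 library kept their direction but no longer passed. Without near-identical copies 8 lists passed for Ecc15, 5 for genotype, 13 for time, 8 for genotype by infection and 4 for infection by time.

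The Ecc15 effect over all libraries (2899 genes) ran from 2279 with the matched pairs as blocks, a model chosen after seeing the data, to 3297 with all pairwise interactions, and was 2282 with no filter. With no filter on low values the genotype effect had 24 genes, time 0, infection by time 4, Ecc15 at 4 h 1134, Ecc15 in control flies 103, Ecc15 in the libraries labelled JHDM2 knockdown 1, and the genotype effect 0 in uninfected flies and 0 after Ecc15. More genes near 0 enter there; the cause was not tested. With all pairwise interactions 1 residual degree of freedom is left, and the genotype effect, time, infection by time, genotype by time and the genotype effect in uninfected and in Ecc15 flies each had 0 genes. Ecc15 in control flies had 1639 and in the labelled libraries 932 in that model.

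With quantile normalization time had 1 gene, and 3 lists passed for genotype (6 with the scaling as deposited) and 9 for time (15 with the scaling as deposited). With a pseudocount of 5 time had 1 gene. Genes at 2-fold in single pairs then numbered 781 and 740 for Ecc15 in control flies at 4 h and 16 h and 678 in the labelled libraries at 16 h. Between genotypes they numbered 241 and 291 in uninfected flies and 262 and 229 after Ecc15 at 4 h and 16 h, as a larger pseudocount shrinks ratios of low genes by construction. With a pseudocount of 0.1 the genotype pairs after Ecc15 had 768 and 704 such genes, genotype by infection had 4 genes, genotype by time 0 and genotype after Ecc15 6. With the filter 5 times higher time had 2 genes, genotype by time 0 and genotype after Ecc15 7. With a robust prior genotype by infection had 2 genes and infection by time 206. With protein-coding genes alone genotype by time had 0 genes, as the 3 are small nucleolar RNA genes, and the genotype effect had 13 in uninfected flies and 4 after Ecc15. With a correlation estimated per list 0 lists passed for the Ecc15 effect, for genotype, for time, for genotype by infection and for infection by time. That version is limited to the residual degrees of freedom of each fit. The cause of these shifts was not tested unless stated.

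Leaving out 1 library at a time leaves fewer residual degrees of freedom, and a combination that loses its library rests on the model. The Ecc15 effect then ran from 1605 (without the labelled Ecc15 16 h library) to 2436 (without the labelled Ecc15 4 h library), and the genotype effect from 12 (without the control uninfected 4 h library) to 78 (without the control Ecc15 4 h library). Time ran from 0 to 5, genotype by infection from 0 to 2, infection by time from 1 to 91, and genotype by time was 0 throughout. Ecc15 at 4 h ran from 419 to 1489, at 16 h from 174 to 2610, in control flies from 3 to 354 and in the labelled libraries from 1 to 33. The genotype effect ran from 0 to 15 in uninfected flies and from 0 to 7 after Ecc15. The unknown depth sets no limit that can be computed here.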

Other observations

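The gene classes described here were chosen after the results were seen, and the tests on their held-out members were written down before the values of those members were looked at. The photoreceptor test with a filter from the other libraries was chosen only after the result was seen.

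Genes of the secretory pathway rose together at 4 h after Ecc15. CaBP1, a protein disulfide isomerase gene, rose by 2.62 ± 0.19 (adjusted p = 0.00285), the lectin chaperone gene Calr by 1.247, the translocon gene Sec61beta by 1.49 and the coat gene Sec23 by 1.08. They belong to 27 held-out genes, of which 24 rose and 0 fell at 4 h (median 1.04, percentile 100 of matched random lists). At 16 h 16 rose and 0 fell (median 0.44). The 5 genes first noticed, Hsc70-3, Gp93, ERp60, Sec22 and Sec24CD, had a median of 1.64 at 4 h. Xbp1, which encodes a regulator of the unfolded protein response, gave 0.15 (adjusted p = 0.309). The class moved beyond its first members, which does not show why. A demand for secreted proteins after infection is a hypothesis that was not tested, since no measure of secretion is part of the data.

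Ribosome biogenesis genes were tested the same way with the opposite outcome. Non1, LTV1 and RpL24-like fell by 1.71, fell by 1.54 and fell by 1.06 after Ecc15. The cytoplasmic ribosomal protein list was set as all symbols starting RpL or RpS. That definition takes in RpL24-like, so its fall is not separate from that list's result. The 23 held-out genes of the class had a median of 0.29 (2 rose, 0 fell), at percentile 96.39, so the fall of the first 3 is not shared by the class. At 4 h 13 of the 23 rose (median 0.54).

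Photoreceptor genes stood high in the control uninfected 4 h library. ninaE was at 104 FPKM there, Arr2 at 39.5 FPKM and Arr1 at 35.0 FPKM, against 16.6, 9.36 and 6.84 FPKM in the control uninfected 16 h library. Of 20 held-out photoreceptor genes 7 passed the filter on low values, and their median log2 ratio of that library to the one at 16 h was 1.39, at percentile 100. That filter is partly decided by the library tested. With the filter and the matching taken from the 6 libraries outside the ratio, 4 held-out genes remained, with a median of 0.81 at percentile 96.48, so whether the class as a whole stood high there is left open. For 5 neuronal genes the median was 0.24, at percentile 72.8 with the filter on all libraries. In the labelled Ecc15 4 h library, against the one at 16 h, the 7 held-out genes gave 0.58 at percentile 98.9, and 6 gave 0.47 at percentile 97.6 with the other filter.

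The hormone gene Burs was at 7.76 to 18.4 FPKM in uninfected libraries and at 45.8 to 89.4 FPKM after Ecc15 (log2 change 2.36 ± 0.21, adjusted p = 0.00213). It is outside the lists and was chosen after its values were seen.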
